A study of Mus musculus with 30 samples.

How the data were processed

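RNA was measured in 30 libraries of 2 muscles, taken 3 days after surgery from male mice in 3 groups: sham, T3 injury and T9 injury. Per the labels' protocols, polyA RNA was made into strand-specific libraries and read as pairs on a NovaSeq instrument. The deposited table holds log2 values for 11249 genes and 30 libraries. Per the submitters' processing notes, the authors used HISAT2 2.1.0, the GRCm38 build, featureCounts, Subread 1.5.1 and limma to make it. The release of the gene annotation and the filter on low genes are not given in the sources used here. The deposited log2 values are log2 CPM with an offset of 0.5 reads (CPM is reads per 1e+06 reads), as the values themselves show: whole reads were recovered for 100% of them within a tolerance of 0.01 reads, with each library scaled only to its own total. Each gene of the file reached 2.34 CPM in at least 4 libraries. Of the gene IDs, 11240 were matched to a symbol and 9 were not.

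Depth is the sum of the recovered reads over genes. Intervals and floors cover counting error only, at a 95% confidence level and with a floor of 3 reads over a group, and reads are not independent molecules. Replicate libraries were compared in pairs before averaging: chi-square per degree of freedom was 9.78 to 621 and Pearson r across genes 0.821 to 0.992, so no pair differed by less than sampling noise.

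Groups, tests, alternatives and the rule for naming genes were fixed before the data were examined. Genes were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a variance trend, two-sided), and p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. A count test was foreseen for counts, but the table holds log2 values. Genes with a log2 value of at least 0 in at least 4 libraries were tested, 11248 in the gastrocnemius and 11249 in the triceps and in both muscles together. The 12 gastrocnemius libraries were fitted together, and so were the 18 triceps libraries with a term for the number 57 or 60 that opens their description. The meaning of that number is not given in the sources used here, and 2 of 6 triceps libraries in each group carry 57. Differences between muscles were tested in the 24 libraries of the 12 mice with both muscles, with the mouse as a block. The number that follows 57 or 60 in a description was taken as that of the mouse, which is an inference. Libraries that share it deviated together from their group means in 11 of 12 cases (r above 0.1, mean 0.322, against -0.113 for other mice of the group). The exception was sham mouse 3 (r = -0.753), whose triceps library correlated at 0.862 with the gastrocnemius library of sham mouse 4, both among the 4 libraries with the lowest median. Whether its mouse number is right is not settled, so counts with the block that move over 1.5 times without this mouse are given also without it. Replicate numbers of the gastrocnemius and the triceps do not always name the same mouse after T3, so mice are named by their triceps replicate.

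Of 49 gene lists fixed beforehand, with 1062 genes in all, 47 were tested with limma's camera with a preset correlation of 0.01. Neutrophil markers and T and NK cell markers had 0 genes in the file. Adjusted p-values of lists were taken over the 47 lists of a comparison. With an estimated correlation, 2 of the list calls within muscles held, those of fast-fibre genes in the gastrocnemius after T3 and after T9. A list's members were also adjusted over the list alone. Named genes were the 8 higher and 8 lower with the largest change at adjusted p under 0.05, a mean log2 value of at least 1 in the higher group and a symbol that is no predicted gene. Up to 4 members of each list with the smallest adjusted p were added, and a panel of 31 genes, 29 of them in the file. Between muscles, 5 genes per direction, list members and limb identity genes could be named. The text gives a part of the genes that rule allows, and results for some of them are not reported here. Genes beyond the rule are said to have been chosen after their values were seen.

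Other settings chosen beforehand were quantile normalization, median centring of each library, no filter or a stricter one (log2 value of at least 2), a pseudocount of 1 CPM, other variance models, library weights, other sets of libraries in the fit, the replicate number as a block, the fit without a block between muscles, label numbers apart, and leaving out each library. For lists they were an estimated correlation and fry. Added after seeing the data were removal of each library's trend on transcript length and GC, the library median as a covariate (the median covariate), voom weights on the recovered reads with and without median-of-ratios scaling, and leaving out the 4 libraries with the lowest median. Added for lists after seeing the data was leaving out each library, and added for the correlation between muscles a simulation of unchanged groups that kept the libraries of a mouse together (100 draws). Data were simulated with 100 genes changed by 1, 100 by 2 (log2) and 32 proteasome subunits up by 1. For T3 in the gastrocnemius the test called 62% and 90% of the 2 gene sets (185 calls, 8 false, 25 subunits). In the triceps it called 61% and 97% (192, 6, 28) and between muscles 27% and 82% (144, 11, 24). A regrouping of triceps sham and T9 libraries called 3763 genes, so real false calls may be more. Gene positions come from the GRCm38 annotation used here.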

Results

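Gene expression was measured by stranded polyA RNA sequencing in muscle of male mice, 3 days after sham surgery or an injury of the spinal cord at the third (T3) or the ninth (T9) thoracic level. The gastrocnemius, a muscle of the hind limb, was sampled in 4 mice per group. The triceps brachii, a muscle of the forelimb, was sampled in 6 mice per group. Library descriptions tie 24 of the 30 libraries to 12 mice with both muscles. The series asks whether the level of the lesion sets the hormonal state and the muscle loss that follow. The deposited table held 11249 genes. Each library had 13.3 to 23.4 M reads in those genes (M for 1e+06), except triceps T3 replicate 5 with 88.8 M.

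Libraries also differed within groups. The median log2 value of a library was 3.90 ± 0.18, 4.17 ± 0.10 and 4.30 ± 0.02 in gastrocnemius sham, T3 and T9 (SD, n = 4) and 3.74 ± 0.28, 3.97 ± 0.13 and 3.91 ± 0.14 in the same triceps groups (SD, n = 6). The 4 lowest medians belonged to triceps sham replicates 3 (3.29) and 4 (3.55), gastrocnemius sham replicate 4 (3.66) and triceps T9 replicate 1 (3.67). Mitochondrially encoded genes took 10.9% ± 1.63, 7.88% ± 0.275 and 8.58% ± 0.787 of reads in gastrocnemius sham, T3 and T9 and 13.4% ± 2.24, 13.2% ± 2.26 and 15.4% ± 1.92 in the triceps. Triceps sham replicate 4 held 705 CPM of the macrophage gene Lyz2 against 9.03 to 26 in the other sham libraries of that muscle, and 85.8 CPM of Ctss against 1.59 to 4.16. The median log2 change over all genes was 0.27 and 0.40 in the gastrocnemius after T3 and T9, 0.23 and 0.17 in the triceps, and -0.11 and 0.05 for T3 against T9. Counts are therefore given also after centring each library on its median.

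The first comparison asked how the gastrocnemius, which lies below both lesions, responded to T3 injury. Genes of muscle protein breakdown rose. Fbxo32, which encodes the ubiquitin ligase atrogin-1, went from 232 ± 81.8 to 1807 ± 452 CPM (SD, n = 4), a log2 change of 3.00 ± 0.29 (SE, limma adjusted p = 1.6e-05). Trim63, which encodes the ligase MuRF1, went from 274 ± 102 to 1736 ± 473 CPM (2.69 ± 0.27, adjusted p = 2.1e-05). Both lay above every sham library in 4 of 4 T3 libraries. Foxo1, a transcription factor that acts on both genes, rose by 2.23 ± 0.29. Of 32 proteasome subunits 30 rose (30 adjusted over the list alone, 21 after centring, camera adjusted p = 5.8e-12, adjusted p = 0.32 with estimated correlation), with Psmd4 at 1.73 ± 0.14 and Psmc4 at 1.63 ± 0.17. Of 28 ubiquitin ligases and atrogenes 16 rose and 0 fell (17 and 0 adjusted over the list alone, 12 and 2 after centring, camera adjusted p = 0.001, adjusted p = 0.57 with estimated correlation). Of 30 autophagy and lysosome genes 15 rose and 0 fell (20 and 0 adjusted over the list alone, 8 and 2 after centring, camera adjusted p = 0.0014, adjusted p = 0.36 with estimated correlation), among them the cathepsins Ctsl (2.43 ± 0.22) and Ctsd (1.60 ± 0.17).

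Genes induced by glucocorticoids, by loss of nerve supply and by oxidative stress rose in the same muscle. Of 32 glucocorticoid-induced genes 25 rose and 1 fell (25 and 2 adjusted over the list alone, 14 and 2 after centring, camera adjusted p = 7.3e-05, adjusted p = 0.32 with estimated correlation), including Cebpb (1.85 ± 0.19), the metallothionein Mt1 (1.94 ± 0.20) and the receptor chaperone Fkbp5 (1.504 ± 0.30). Of 22 denervation-induced genes 12 rose (12 adjusted over the list alone, 11 after centring, camera adjusted p = 0.00045, adjusted p = 0.43 with estimated correlation). They included Gadd45a (3.33 ± 0.16, adjusted p = 1.2e-07), the deacetylase Hdac4 (2.96 ± 0.25), the acetylcholine receptor subunit Chrna1 (2.19 ± 0.26) and the myogenic factor Myog (3.13 ± 0.48, or 3.81 without T3 replicate 1). Of 21 antioxidant genes 16 rose and 1 fell (16 and 1 adjusted over the list alone, 15 and 1 after centring, camera adjusted p = 5.9e-05, adjusted p = 0.096 with estimated correlation), with Gclm of glutathione synthesis at 1.67 ± 0.19. Of 23 ribosome biogenesis genes 18 rose (21 adjusted over the list alone, 12 after centring, camera adjusted p = 4.3e-05, adjusted p = 0.49 with estimated correlation), with nucleolin, Ncl, at 1.35 ± 0.14. The 8 largest increases were Krt80 (4.38 ± 0.47), the cell cycle inhibitor Cdkn1a (3.98 ± 0.37), Eda2r (3.70), Dll1 (3.52), Ankrd1 (3.48), Arrdc3 (3.40), Tnfrsf23 (3.37) and Prune2 (3.37). Cdkn1a lies on chromosome 17, 29090976 to 29100727 of GRCm38. The translation repressor Eif4ebp1 rose by 2.35 ± 0.17. Cd68, a lysosomal protein used as a macrophage marker, rose by 3.01 ± 0.47 as 1 of 10 macrophage markers (camera adjusted p = 0.67, adjusted p = 0.91 with estimated correlation).

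Lists of respiratory chain, TCA cycle, glycolysis and fibre type genes ranked below other genes. Of 48 nuclear-encoded respiratory chain genes 24 fell (37 adjusted over the list alone, 35 after centring, camera adjusted p = 6.7e-17, adjusted p = 0.32 with estimated correlation), with Cyc1 at -0.76 ± 0.13, Cycs at -1.18 ± 0.29 and Cox7a1 at -1.38 ± 0.36. Of 15 mitochondrially encoded genes 7 fell (8 adjusted over the list alone, 12 after centring, camera adjusted p = 1.1e-06, adjusted p = 0.32 with estimated correlation), but with the length and GC trend removed 1 was lower, the median went from -0.47 to 0.054 and the list was not called (adjusted p = 0.68). Of 20 TCA cycle genes 1 rose and 3 fell (0 and 2 adjusted over the list alone, 0 and 12 after centring, camera adjusted p = 0.001, adjusted p = 0.39 with estimated correlation), with Idh3a at -0.71 ± 0.13. Of 25 glycolysis and glycogen genes 3 rose and 9 fell (3 and 9 adjusted over the list alone, 3 and 11 after centring, camera adjusted p = 0.00028, adjusted p = 0.5 with estimated correlation). The glycolytic enzymes Eno3 (-1.40 ± 0.16), Tpi1 (-1.51), Ldha (-1.34) and Pgam2 (-1.33) fell, and Gbe1, the glycogen branching enzyme, rose by 2.25 ± 0.21. Of 20 fast-fibre genes 1 rose and 9 fell (1 and 10 adjusted over the list alone, 0 and 10 after centring, camera adjusted p = 1.1e-06, adjusted p = 0.023 with estimated correlation), and of 13 slow-fibre genes 4 fell (4 adjusted over the list alone, 5 after centring, camera adjusted p = 0.0034, adjusted p = 0.59 with estimated correlation). The myosin light chains Mylpf and Myl2 stood at -1.24 ± 0.25 and -2.31 ± 0.46. Of 30 collagen and matrix genes 4 rose and 6 fell (4 and 6 adjusted over the list alone, 3 and 14 after centring, camera adjusted p = 0.0016, adjusted p = 0.62 with estimated correlation), with Col3a1 at -1.49 ± 0.21 and Postn at -2.05 ± 0.22. Of 14 fibroblast markers 1 rose and 3 fell (1 and 4 adjusted over the list alone, 1 and 5 after centring, camera adjusted p = 0.021, adjusted p = 0.58 with estimated correlation), a list not called without sham replicates 3 (adjusted p = 0.053) or 4 (0.085), with the length and GC trend removed (0.073) or with the median covariate (0.7). With the median covariate the lists of the respiratory chain (adjusted p = 0.12), mitochondrially encoded genes (0.069), slow-fibre genes (0.41) and polyamine and androgen-dependent genes (0.096) were not called. Neither were mitochondrially encoded genes (0.21), glycolysis (0.075) and fast-fibre genes (0.074) after quantile normalization, nor slow-fibre genes with the length and GC trend removed (0.056).

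Polyamine genes moved in both directions after T3. Smox, which encodes spermine oxidase, went from 737 ± 282 to 62.9 ± 7.89 CPM (-3.48 ± 0.23), Amd1 changed by -2.16 ± 0.23 and the spermidine synthase Srm rose by 1.45 ± 0.21. Of 16 polyamine and androgen-dependent genes 3 rose and 6 fell (3 and 6 adjusted over the list alone, 3 and 8 after centring, camera adjusted p = 0.0017, adjusted p = 0.14 with estimated correlation). Lrrc52 had 199 reads over the 4 sham libraries and 0 over the 4 T3 libraries, at least 57.9-fold lower against a floor of 3 reads over the group, with 46.6-fold as the lower 95% counting limit of the ratio itself. The other large decreases were Nmrk2 (-4.14 ± 0.45), the ketone body enzyme Bdh1 (-4.05 ± 0.38), Fgfbp1 (-3.94), Nrep (-3.87), Nr4a3 (-3.47) and Mettl21c (-3.46). The growth factor Igf1 changed by -1.69 ± 0.32. Of 43 ribosomal protein genes 1 rose, while the list ranked below other genes with a median of -0.17 (camera adjusted p = 0.0014, adjusted p = 0.83 with estimated correlation). Without gastrocnemius sham replicate 4 that list lay 0.04 above other genes (adjusted p = 0.68), and 0.78 above them with the median covariate (8.3e-10). In all, limma called 3794 of 11248 genes, 3046 higher and 748 lower (1642 and 1626 after centring). The count was 2357 with only the groups compared in the fit and 2079 with the median covariate.

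Genes that muscle expresses on losing its nerve supply rose in the gastrocnemius after T9 injury. The acetylcholine receptor subunits Chrnd and Chrna1 changed by 4.84 ± 0.39 and 3.32 ± 0.26 and Myog by 4.68 ± 0.48. Gadd45a went from 24.4 ± 1.29 to 267 ± 12 CPM (SD, n = 4, log2 change 3.45 ± 0.16, limma adjusted p = 7.2e-08) and Hdac4 rose by 3.32 ± 0.25. Each lay above every sham library in 4 of 4 T9 libraries. Of 22 denervation-induced genes 16 rose and 1 fell (16 and 1 adjusted over the list alone, 15 and 1 after centring, camera adjusted p = 2.2e-05, adjusted p = 0.35 with estimated correlation). The other genes among the 8 largest increases were Rrad (5.67 ± 0.83), Ankrd1 (5.19), Aif1l (4.77), Cdkn1a (4.03), Lpin2 (3.90) and Krt80 (3.89). Fbxo32 rose by 2.29 ± 0.29 and Trim63 by 1.61 ± 0.27. Of 32 proteasome subunits 21 rose (24 adjusted over the list alone, 6 after centring, camera adjusted p = 0.0002, adjusted p = 0.68 with estimated correlation), with Psmd4 at 1.10 ± 0.14. Ctsl rose by 2.28 ± 0.22.

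Antioxidant and unfolded protein response genes rose after T9 too. Of 21 antioxidant genes 17 rose and 1 fell (18 and 1 adjusted over the list alone, 13 and 1 after centring, camera adjusted p = 0.00028, adjusted p = 0.15 with estimated correlation), with the haem oxygenase Hmox1 at 2.57 ± 0.32. Of 20 unfolded protein response genes 17 rose (17 adjusted over the list alone, 6 after centring, camera adjusted p = 0.0029, adjusted p = 0.68 with estimated correlation), with Xbp1 at 1.01 ± 0.13 and Canx at 1.22 ± 0.18. Of 23 ribosome biogenesis genes 20 rose (21 adjusted over the list alone, 14 after centring, camera adjusted p = 2.2e-05, adjusted p = 0.52 with estimated correlation), with Ncl at 1.22 ± 0.14. Of 32 glucocorticoid-induced genes 15 rose and 1 fell (16 and 1 adjusted over the list alone, 11 and 3 after centring, camera adjusted p = 0.16, adjusted p = 0.74 with estimated correlation), so the list was not called. It was called after centring (adjusted p = 0.022), after quantile normalization (0.013) and with the median covariate (0.0033). Mt1 rose by 1.99 ± 0.20, Fkbp5 stood at 0.44 ± 0.30 (adjusted p = 0.24) and Klf15 at 0.55 ± 0.26 (adjusted p = 0.095). Without T9 replicate 1 Klf15 passed at 0.72 (adjusted p = 0.043). Of 10 macrophage markers 4 rose (4 adjusted over the list alone, 1 after centring, camera adjusted p = 0.85, adjusted p = 0.97 with estimated correlation), namely Cd68 (3.22 ± 0.47), Lgals3 (0.98 ± 0.29), Mrc1 (0.84 ± 0.24) and Csf1r (0.75 ± 0.23). The list was called higher with the median covariate (adjusted p = 0.031). Mrc1 did not pass without sham replicate 1 (adjusted p = 0.05), nor Csf1r without sham replicate 1 (0.058) or T9 replicates 2 (0.057) and 4 (0.057).

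Genes of oxidative and glycolytic metabolism fell after T9. Of 48 nuclear-encoded respiratory chain genes 40 fell (43 adjusted over the list alone, 47 after centring, camera adjusted p = 3e-35, adjusted p = 0.15 with estimated correlation), among them Cyc1 (-0.95 ± 0.13) and Cox5a (-0.81 ± 0.13). Of 20 TCA cycle genes 1 rose and 7 fell (1 and 7 adjusted over the list alone, 0 and 15 after centring, camera adjusted p = 7.4e-09, adjusted p = 0.15 with estimated correlation), with Idh3a at -1.08 ± 0.13 and Mdh1 at -1.21 ± 0.17. Of 25 glycolysis and glycogen genes 2 rose and 10 fell (2 and 10 adjusted over the list alone, 1 and 15 after centring, camera adjusted p = 2.6e-10, adjusted p = 0.24 with estimated correlation), with Eno3 at -1.82 ± 0.16, Tpi1 at -1.85 and Pgam2 at -1.37. Of 31 fatty acid genes 1 rose and 10 fell (1 and 10 adjusted over the list alone, 1 and 14 after centring, camera adjusted p = 1.7e-07, adjusted p = 0.28 with estimated correlation), with the lipid carrier Fabp3 at -2.09 ± 0.29 and the lipase Lpl at -1.71 ± 0.18. Of 20 fast-fibre genes 1 rose and 9 fell (1 and 9 adjusted over the list alone, 0 and 13 after centring, camera adjusted p = 1.7e-07, adjusted p = 0.016 with estimated correlation), and of 13 slow-fibre genes 5 fell (5 adjusted over the list alone, 5 after centring, camera adjusted p = 4.9e-05, adjusted p = 0.52 with estimated correlation), with Myl2 at -3.53 ± 0.46 and Myl3 at -1.66 ± 0.37. The other large decreases were Bdh1 (-4.67 ± 0.38), Dok5 (-3.76), the mitochondrial regulator Perm1 (-3.67), Nmrk2 (-3.24), Fgfbp1 (-3.12) and Nrep (-3.01). Lrrc52 had 3 reads over the 4 T9 libraries, with sham 60.39-fold higher per read sequenced (95% counting interval 20.4 to 295). The immediate early phosphatase Dusp1 changed by -2.06 ± 0.18 and Igf1 by -0.91 ± 0.32. Igf1 did not pass without sham replicates 2 (adjusted p = 0.051), 3 (0.056) or 4 (0.067) or T9 replicates 1 (0.1), 2 (0.057) or 4 (0.097).

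With the median covariate the T9 lists of the respiratory chain (adjusted p = 0.13), slow-fibre genes (0.54) and the unfolded protein response (0.43) were not called, nor that of fast-fibre genes after quantile normalization (0.16). In all, limma called 4864 of 11248 genes in the gastrocnemius after T9, 4226 higher and 638 lower (1240 and 1399 after centring). The total was 2639 after centring, 2719 after quantile normalization and 1388 with the median covariate. Of 43 ribosomal protein genes 1 rose, while the list ranked below other genes with a median of -0.02 (camera adjusted p = 0.00092, adjusted p = 0.83 with estimated correlation). Without gastrocnemius sham replicate 4 the list lay 0.07 above other genes (adjusted p = 0.54), and 1.33 above them with the median covariate (7.4e-19).

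**Figure D1:**
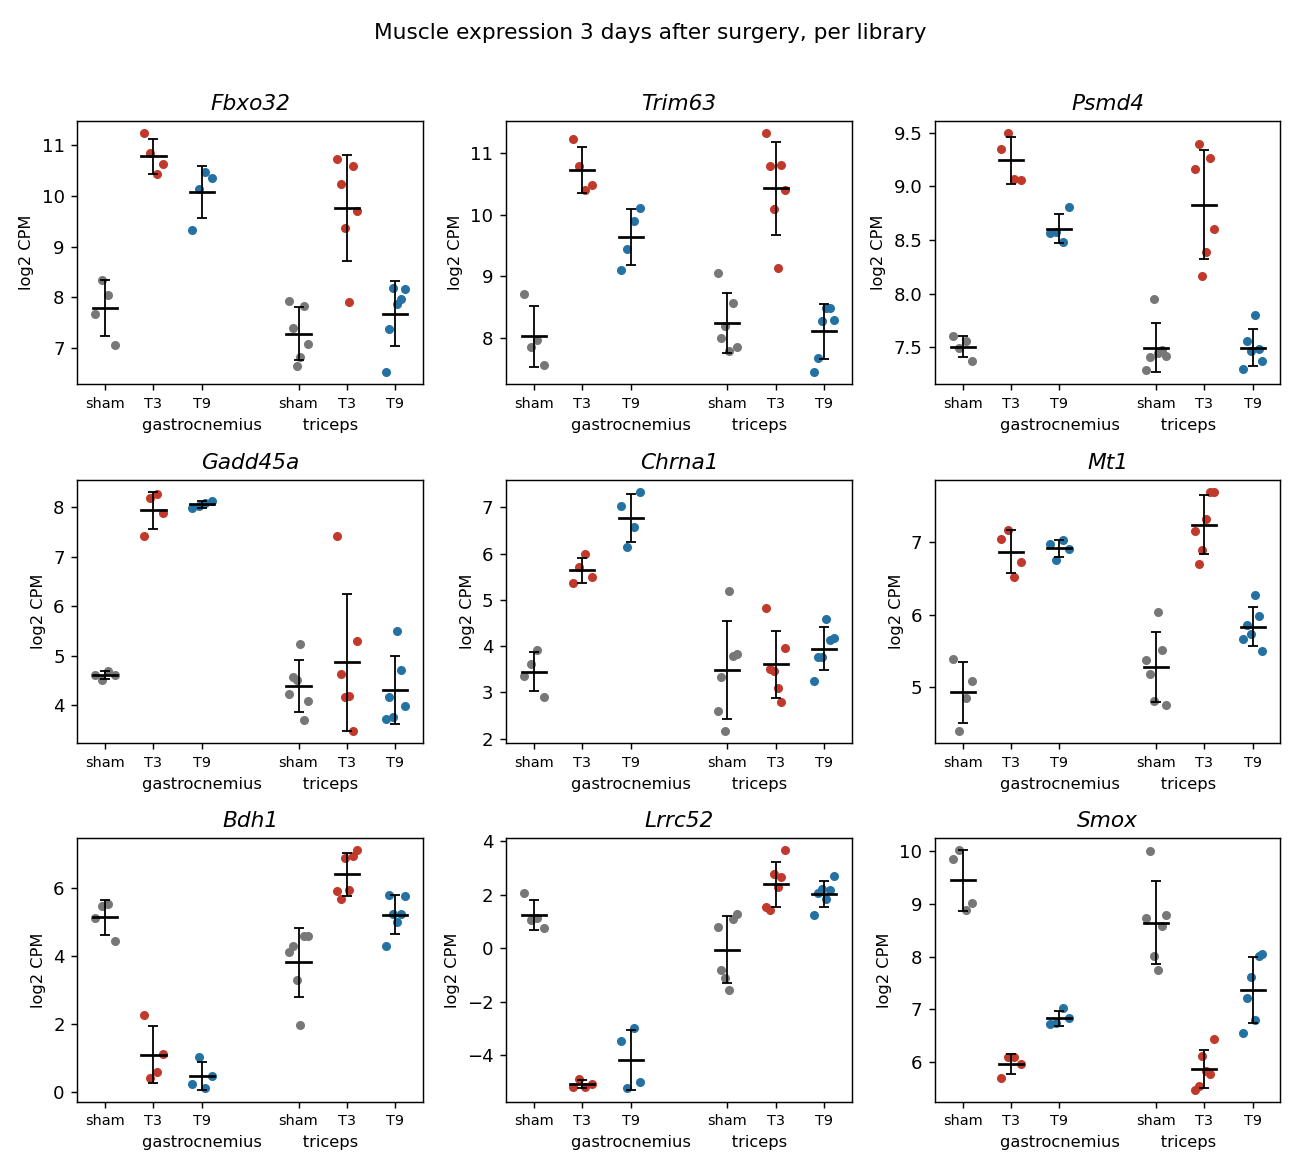
Log2 CPM of 9 genes in each library (points), with the mean (line) and SD (bars) per group of 4 gastrocnemius or 6 triceps libraries, after sham surgery (grey), T3 (red) or T9 (blue) injury. In the gastrocnemius all T3 libraries lie above all sham libraries for Fbxo32, Trim63, Psmd4, Gadd45a and Chrna1, and the T3 points of Lrrc52 stand for 0 reads.

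A direct test set T3 against T9 in the gastrocnemius. Mustn1 was higher after T3 by 2.17 ± 0.40 (SE, n = 4, limma adjusted p = 0.021). Higher too were Perm1 (2.17 ± 0.41), Fabp3 (1.74 ± 0.29), Slc25a34 (1.87), the acetyl-CoA synthetase Acss2 (1.73), Wdr62 (1.72) and Fabp3-ps1 (1.94), a pseudogene of Fabp3 whose reads are hard to tell from those of Fabp3, so that its value is uncertain. Lower after T3 were Nr4a3 (-4.17 ± 0.82), Fam83d (-2.62), Chrnd (-2.21 ± 0.39), the water channel Aqp4 (-2.65), Scx (-1.93), Tuba1b (-1.77) and Gdap1 (-1.68). Of 31 fatty acid genes 5 were higher (13 adjusted over the list alone, 7 after centring, camera adjusted p = 1.5e-16, adjusted p = 0.3 with estimated correlation), with Hadh at 0.85 ± 0.15. Of 32 proteasome subunits 2 were higher (8 adjusted over the list alone, 3 after centring, camera adjusted p = 7.8e-18, adjusted p = 0.39 with estimated correlation), with Psmd4 at 0.63 ± 0.14. Of 32 glucocorticoid-induced genes 2 were higher (4 adjusted over the list alone, 3 after centring, camera adjusted p = 6.6e-07, adjusted p = 0.39 with estimated correlation), Klf9 (0.62) and Pik3r1 (1.17), and of 25 glycolysis and glycogen genes 2 were higher (5 adjusted over the list alone, 5 after centring, camera adjusted p = 7.9e-06, adjusted p = 0.58 with estimated correlation), with Ugp2 at 1.14. Eif4ebp1 was higher by 0.95 ± 0.17. Of 48 respiratory chain genes no member passed by limma (5 at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone, 1 and 0 after centring, camera adjusted p = 5.8e-10, adjusted p = 0.62 with estimated correlation), with a median of 0.21. Of 22 denervation-induced genes 2 were lower (6 adjusted over the list alone, 2 after centring, camera adjusted p = 0.0074, adjusted p = 0.68 with estimated correlation), with Chrna1 at -1.13 ± 0.26. Those 2 lists were not called with the median covariate (adjusted p = 0.76 and 0.088). Fbxo32 (0.71 ± 0.29, adjusted p = 0.26), Trim63 (1.09, 0.065), Myog (-1.55, 0.12) and Gadd45a (-0.12, 0.79) did not pass. T3 replicate 1 held 9.22 CPM of Myog against 52 to 70.9 in the other T3 libraries, and without it Myog stood at -0.87 (adjusted p = 0.072). In all limma called 183 genes, 82 higher and 101 lower (172 and 84 after centring). The count rested on single libraries, at 15, 30 and 101 without T3 replicates 1, 2 and 4 and 20, 60, 17 and 11 without T9 replicates 1 to 4. Of the genes named here 2 of the 21 past the test stayed past it whichever library was left out, namely Aqp4 and Gdap1. The others fell short in 19 cases (adjusted p = 0.064 to 0.17) without T3 replicate 1, 16 cases (0.056 to 0.14) without T3 replicate 2, 2 cases (0.054 to 0.056) without T3 replicate 3 and 4 cases (0.065 to 0.11) without T3 replicate 4. They fell short in 18 cases (adjusted p = 0.052 to 0.14) without T9 replicate 1, 10 cases (0.05 to 0.12) without T9 replicate 2, 19 cases (0.067 to 0.14) without T9 replicate 3 and 19 cases (0.058 to 0.16) without T9 replicate 4.

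The triceps lies above both lesions. After T3 injury its protein breakdown genes rose. Fbxo32 went from 165 ± 59.9 to 1031 ± 557 CPM (SD, n = 6), a log2 change of 2.47 ± 0.39 (limma adjusted p = 0.0003), and lay above every sham library in 5 of 6 T3 libraries. Trim63 went from 319 ± 118 to 1519 ± 684 CPM (2.18 ± 0.31, 6 of 6). Of 32 proteasome subunits 27 rose (28 adjusted over the list alone, 15 after centring, camera adjusted p = 4.4e-13, adjusted p = 0.38 with estimated correlation), with Psmd8 at 1.18 ± 0.13 and Psmd2 at 1.62 ± 0.22. Of 28 ubiquitin ligases and atrogenes 12 rose (15 adjusted over the list alone, 9 after centring, camera adjusted p = 0.004, adjusted p = 0.71 with estimated correlation), a list not called with the median covariate (adjusted p = 0.12). Of 30 autophagy and lysosome genes 15 rose and 0 fell (18 and 0 adjusted over the list alone, 8 and 1 after centring, camera adjusted p = 0.0015, adjusted p = 0.43 with estimated correlation), with Ctsd at 1.28 ± 0.12. Of 32 glucocorticoid-induced genes 19 rose (24 adjusted over the list alone, 15 after centring, camera adjusted p = 3.4e-05, adjusted p = 0.47 with estimated correlation), with Mt1 at 1.96 ± 0.22, Klf15 at 1.41 and Fkbp5 at 1.36. Eif4ebp1 rose by 1.94 ± 0.18, Cdkn1a by 1.67 ± 0.36 and Ncl by 0.89 ± 0.16.

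Genes of fatty acid use and amino acid catabolism rose in the triceps after T3. Of 31 fatty acid genes 22 rose (22 adjusted over the list alone, 16 after centring, camera adjusted p = 5.2e-07, adjusted p = 0.39 with estimated correlation), with Etfdh at 1.36 ± 0.16 and the fatty acid transporter Cd36 at 1.245 ± 0.17. Of 22 amino acid catabolism genes 17 rose and 0 fell (19 and 0 adjusted over the list alone, 10 and 2 after centring, camera adjusted p = 1.1e-05, adjusted p = 0.47 with estimated correlation), with Prodh at 1.14 ± 0.17 and Dbt at 0.82 ± 0.13. Bdh1 rose from 16.6 ± 8.21 to 92.4 ± 38.9 CPM (2.60 ± 0.34). Of 20 TCA cycle genes 8 rose (10 adjusted over the list alone, 5 after centring, camera adjusted p = 0.048, adjusted p = 0.77 with estimated correlation), with Mdh1 at 1.08 ± 0.18 and Idh2 at 1.09 ± 0.21. That list was not called without sham replicates 4 (adjusted p = 0.11), 5 (0.052) or 6 (0.07), T3 replicates 3 (0.074), 4 (0.1) or 6 (0.11), or T9 replicates 1 (0.054), 2 (0.053) or 3 (0.05), nor after centring (0.12) or with the length and GC trend removed (0.058). Of 48 respiratory chain genes 2 rose, while the list ranked below other genes with a median of -0.03 (0 adjusted over the list alone, 0 after centring, camera adjusted p = 0.026, adjusted p = 0.79 with estimated correlation). Its call was lost without sham replicate 3 (adjusted p = 0.45) or T3 replicates 1 (0.35) and 2 (0.11), after quantile normalization (0.15), with the length and GC trend removed (0.27) and without the 4 low-median libraries (0.89), and with the median covariate the list lay 0.24 above other genes (0.00027). Of 22 denervation-induced genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, 3 and 1 after centring, camera adjusted p = 0.94, adjusted p = 0.98 with estimated correlation). Gadd45a stood at 0.48 ± 0.49 (adjusted p = 0.48), or -0.017 without T3 replicate 1 (0.98), and Myog at 0.83 ± 0.45 (0.18). Without triceps sham replicate 4 (27.6 CPM of Myog against 2.96 to 5.49 in other sham libraries) Myog stood at 1.31 (adjusted p = 0.0073).

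Lists of fast-fibre, collagen and matrix, and polyamine and androgen-dependent genes ranked below other genes in the triceps after T3. Of 20 fast-fibre genes 8 fell (8 adjusted over the list alone, 10 after centring, camera adjusted p = 2.7e-07, adjusted p = 0.15 with estimated correlation), with the calcium buffer Pvalb at -1.58 ± 0.26 and Tpm1 at -0.92 ± 0.16. Of 30 collagen and matrix genes 6 fell (6 adjusted over the list alone, 11 after centring, camera adjusted p = 3.8e-06, adjusted p = 0.51 with estimated correlation), with Col3a1 at -1.95 ± 0.53. Of 14 fibroblast markers 1 rose and 2 fell (1 and 3 adjusted over the list alone, 0 and 4 after centring, camera adjusted p = 0.012, adjusted p = 0.64 with estimated correlation), a list not called without sham replicate 4 (adjusted p = 0.066), without the 4 low-median libraries (0.35) or with the median covariate (0.52). Of 16 polyamine and androgen-dependent genes 2 rose and 7 fell (3 and 8 adjusted over the list alone, 2 and 8 after centring, camera adjusted p = 0.00081, adjusted p = 0.39 with estimated correlation), with Smox at -2.78 ± 0.31 and Amd1 at -1.37 ± 0.27. Igf1 changed by -1.97 ± 0.31, Ldha by -1.19 ± 0.15 and the glycerol phosphate dehydrogenase Gpd1 by -1.58 ± 0.31. Beside Bdh1, the largest increases were Krt80 (3.91 ± 0.47), Cd68 (3.78 ± 0.69), Gpnmb (3.59 ± 0.69), Dusp18 (3.23), Hgs (2.88), Egln3 (2.62) and Slc25a34 (2.59). Large decreases were, beside Smox, those of Nrep (-3.75 ± 0.40), Mettl21c (-3.04), Nmrk2 (-2.78), Gdap1 (-2.66), Aqp4 (-2.57) and the immunoglobulin gene Ighm (-2.26). Of 10 macrophage markers 1 rose (1 adjusted over the list alone, 1 after centring, camera adjusted p = 0.12, adjusted p = 0.79 with estimated correlation), and without sham replicate 1 the list was called lower (adjusted p = 0.038). Lgals3 stood at -0.10 ± 0.70, and without sham replicate 4 at 0.80 (adjusted p = 0.029). Of 43 ribosomal protein genes no member passed by limma (1 at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone, 0 and 0 after centring, camera adjusted p = 2.7e-07, adjusted p = 0.72 with estimated correlation), with a median of -0.32. With the median covariate that list lay 0.29 above other genes (adjusted p = 0.00027), and without the 4 low-median libraries 0.020 above them (0.92). In all, limma called 2624 of 11249 genes, 2138 higher and 486 lower (1140 and 894 after centring). It called 1247 within the 12 libraries of label number 60 and 684 within the 6 of number 57.

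After T9 injury few genes of the triceps passed the test. limma called 1 of 11249 genes, with 1185 at an unadjusted p under 0.05, and limma with voom weights on the recovered reads called 0. It called 230 with library weights, 56 with all 30 libraries in one fit, 15 with the median covariate, 7 with the length and GC trend removed and 0 with the replicate number as a block. The gene called, Gm5532 (1.44 ± 0.20, SE, n = 6, adjusted p = 0.012, above every sham library in 6 of 6 T9 libraries), was chosen after its values were seen. It was lost without T9 replicates 1 (adjusted p = 0.057), 2 (0.051) or 4 (0.059), which left a count of 0 each. The count was 3, 2, 2 and 4 without sham replicates 1, 2, 4 and 5, and 7 and 5 without T9 replicates 5 and 6. Fbxo32 stood at 0.40 ± 0.39 (adjusted p = 0.65), Trim63 at -0.14 ± 0.31 (0.83), Mt1 at 0.55 ± 0.22 (0.42) and Fkbp5 at 0.28 ± 0.29 (0.66). Tsc22d3 stood at 0.75 ± 0.18 (0.15), Cdkn1a at 0.17 ± 0.36 (0.82), Igf1 at -0.56 ± 0.31 (0.52) and Amd1 at -0.27 ± 0.27 (0.65). Of 47 lists 11 were called with the preset correlation, and 0 with an estimated one. The lists of ribosomal proteins (camera adjusted p = 1.4e-16, adjusted p = 0.96 with estimated correlation) and fast-fibre genes (camera adjusted p = 0.00024, adjusted p = 0.4 with estimated correlation) ranked lower and that of immediate early genes (camera adjusted p = 0.0042, adjusted p = 0.96 with estimated correlation) higher. In each of them limma passed 0 members, with 0, 5 and 7 at an unadjusted p under 0.05, and adjusted over the list alone it passed 1 immediate early gene. The immediate early list was not called without sham replicate 6 (adjusted p = 0.093) or with the median covariate (0.11), nor the fast-fibre list after quantile normalization (0.39). The ribosomal list was not called without the 4 low-median libraries (0.31), and with the median covariate it lay 0.16 above other genes (0.00071). The macrophage list ranked lower (camera adjusted p = 0.0029, adjusted p = 0.96 with estimated correlation), and without sham replicate 4 it lay 0.20 above other genes (adjusted p = 0.68), and it was not called after centring (0.098), with the length and GC trend removed (0.15) or with the median covariate (0.79).

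The T3 and T9 triceps were then compared directly. Trim63 was higher after T3 by 2.31 ± 0.31 (SE, n = 6, limma adjusted p = 0.00034, above every T9 library in 6 of 6 T3 libraries) and Fbxo32 by 2.08 ± 0.39. Of 32 proteasome subunits 24 were higher (30 adjusted over the list alone, 16 after centring, camera adjusted p = 1.4e-24, adjusted p = 0.12 with estimated correlation), among them Psmd8 (1.08 ± 0.13) and Psmd4 (1.33 ± 0.19). Of 28 ubiquitin ligases and atrogenes 5 were higher (7 adjusted over the list alone, 7 after centring, camera adjusted p = 0.00034, adjusted p = 0.52 with estimated correlation). Of 32 glucocorticoid-induced genes 9 were higher (14 adjusted over the list alone, 7 after centring, camera adjusted p = 2.9e-06, adjusted p = 0.36 with estimated correlation), with Mt1 at 1.41 ± 0.22. Of 31 fatty acid genes 12 were higher (15 adjusted over the list alone, 9 after centring, camera adjusted p = 2.8e-09, adjusted p = 0.28 with estimated correlation). Eif4ebp1 (1.90 ± 0.18), the folate enzyme Mthfd2 (1.52 ± 0.27), Cdkn1a (2.83-fold, adjusted p = 0.015), Ugp2 (1.14) and Gbe1 (1.497) were higher as well. Beside Trim63, the largest increases were Gpnmb (3.58 ± 0.69), Krt80 (3.15), Cd68 (3.01 ± 0.69), Hgs (2.37), Slc25a34 (2.15), Depp1 (2.12) and Wdr62 (2.22), the last not called without T3 replicate 5 (adjusted p = 0.051). Large decreases were those of Fam83d (-3.11 ± 0.67), Nrep (-2.67), Aqp4 (-2.45), Gdap1 (-2.33), Cntnap2 (-2.22), Myhas (-2.02) and Mettl21c (-1.94). Of 20 fast-fibre genes 5 were lower (7 adjusted over the list alone, 3 after centring, camera adjusted p = 8.4e-05, adjusted p = 0.21 with estimated correlation), with the calcium store protein Casq1 at -1.09 ± 0.23. Gpd1 (-1.72 ± 0.31) and Igf1 (-1.41 ± 0.31) were lower. Of 14 fibroblast markers 3 were lower (4 adjusted over the list alone, 4 after centring, camera adjusted p = 0.00022, adjusted p = 0.36 with estimated correlation), with Pi16 at -1.21 ± 0.21. Of 11 adipocyte markers 0 were higher and 2 were lower (1 and 5 adjusted over the list alone, 0 and 1 after centring, camera adjusted p = 0.0029, adjusted p = 0.36 with estimated correlation), among them Adipoq (-1.02 ± 0.29). Adipoq did not pass without T3 replicates 1 (adjusted p = 0.078), 2 (0.11), 3 (0.09) or 5 (0.11) or T9 replicates 1 (0.077), 4 (0.087), 5 (0.12) or 6 (0.083). Of 30 collagen and matrix genes no member passed by limma (6 at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone, 0 and 2 after centring, camera adjusted p = 0.0004, adjusted p = 0.57 with estimated correlation), with a median of -0.37. In all 855 genes passed, 557 higher and 298 lower (546 and 433 after centring). The count was 50 within label number 60 and 314 within 57, and 539 without T3 replicate 5, the library with the most reads.

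**Figure D2:**
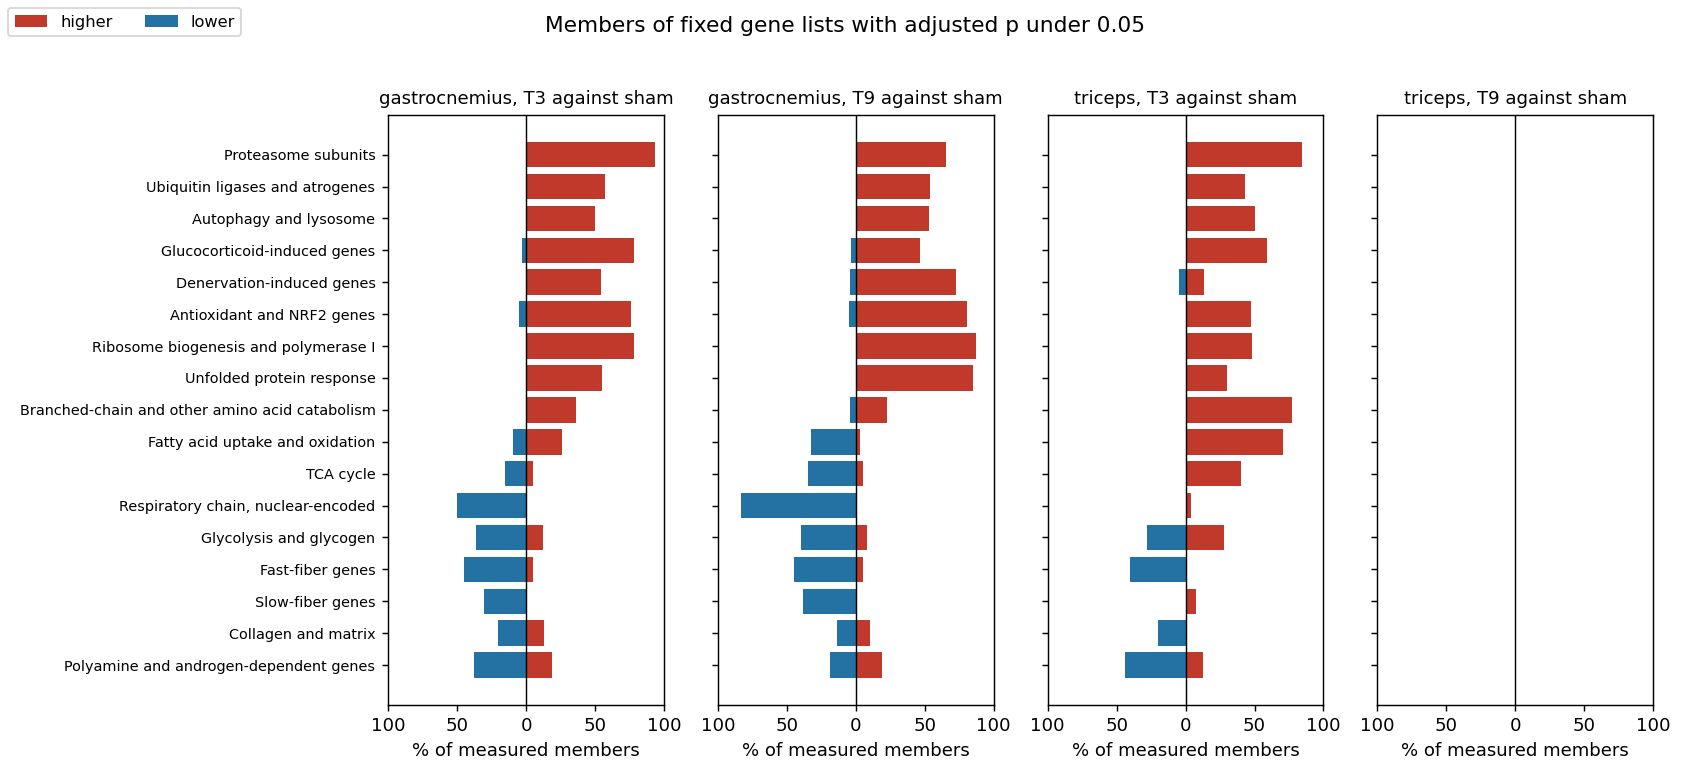
Share of the measured members of 17 gene lists with adjusted p under 0.05, in percent, higher (red, right of the line) or lower (blue, left of it), in each muscle after T3 or T9 injury against sham, from values as deposited. Proteasome subunits rose in 30 of 32 cases after T3 in the gastrocnemius and in 27 of 32 in the triceps (21 and 15 after centring), and the triceps panel for T9 is empty because limma passed 0 members of these lists.

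Effects of the injuries were set side by side across genes, which are not independent replicates. In the gastrocnemius, Fbxo32, Trim63 and Gadd45a were among 2598 genes higher after both injuries (901 after centring). Bdh1 and Nmrk2 were among 400 lower after both (986 after centring). The T3 and T9 effects correlated with r = 0.839 (rho = 0.837). Unchanged groups simulated against the same sham libraries gave a mean r of 0.488 (highest 1, a value the residuals give by construction where a drawn injury group is a real group), and sham libraries divided between the effects gave 0.633 (0.404 to 0.764). The covariance was 0.332 against 0.031 in the simulation (highest 0.125). In the triceps r was 0.632 (rho = 0.637), against a mean of 0.483 (highest 0.909) in the simulation and 0.321 (-0.064 to 0.543) with divided sham libraries. Its covariance was 0.0909 against 0.0317 (highest 0.134), so both triceps values lay within the range of unchanged groups. Between muscles, which share mice and no library, 1488 genes were higher in both after T3 (688 after centring). Lower in both were 288 (584), and 30 (39) were opposite. Trim63 and Psmd4 were among those higher and Smox and Nrep among those lower. The T3 effects of the muscles correlated with r = 0.702 (rho = 0.712), at 0.696 with triceps libraries of label number 60 and 0.433 with those of 57, which share no mouse with the gastrocnemius. Unchanged groups simulated with the shared mice kept together gave a mean r of 0.263 (highest 0.834) and a mean covariance of 0.0183 (highest 0.114), against 0.233 observed. The T9 effects correlated with r = 0.381 (rho = 0.425), at 0.428 and -0.229, with a simulated mean r of 0.225 (highest 0.818) and a covariance of 0.0655 against 0.0164 (highest 0.107).

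Whether the muscles responded differently was tested in the 12 mice with both muscles, 4 per group, with each mouse as a block and mice named by their triceps replicate. After T3, lists of fatty acid and TCA cycle genes had a lower effect in the gastrocnemius than in the triceps. Bdh1 differed by -6.73 ± 0.46 (SE, limma adjusted p = 7.7e-06), Lpl by -1.86 ± 0.20, the fatty acid regulator Ppara by -2.41 ± 0.37, Idh2 by -1.75 ± 0.25 and Mdh1 by -1.83 ± 0.28. Of 31 fatty acid genes 0 had a higher effect and 7 had a lower one (2 and 15 adjusted over the list alone, 0 and 4 after centring, camera adjusted p = 2.6e-08, adjusted p = 0.61 with estimated correlation), and of 20 TCA cycle genes 2 had a lower one (10 adjusted over the list alone, 4 after centring, camera adjusted p = 2.7e-10, adjusted p = 0.57 with estimated correlation). Lower effects held also for the fast myosin Myh2 (-3.56 ± 0.57), Gbp10 (-4.29), Dusp18 (-3.51) and Lrrc52 (-9.02, a value that depends on the offset of 0.5 reads). Higher effects held for the activin antagonist Fst (2.33 ± 0.37), Sox4 (2.36), Cebpa (1.73), Blnk (1.71) and Ccdc136 (1.65). In all 140 genes passed, 16 higher and 124 lower (60 and 188 after centring). The count was 75 without the block, 39 without the mice of low-median libraries, and 68, 80, 54 and 80 without sham mouse 4 and T3 mice 2, 3 and 4. Without T3 mouse 3 Sox4 (adjusted p = 0.12), Cebpa (0.17), Blnk (0.11) and Ccdc136 (0.069) did not pass. Sox4, Cebpa and Blnk did not pass either without sham mouse 4 (0.092, 0.11, 0.086), T3 mouse 2 (0.11, 0.079, 0.091) or T3 mouse 4 (0.096, 0.11, 0.091), nor Cebpa and Blnk without sham mouse 1 (0.081, 0.067), nor Sox4 and Cebpa without sham mouse 2 (0.054, 0.083).

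After T9, genes linked to loss of nerve supply had a higher effect in the gastrocnemius than in the triceps. Gadd45a differed by 3.79 ± 0.72 (SE, 4 mice per group, limma adjusted p = 0.0079), Aif1l by 4.55 ± 0.99, Chrnd by 3.85 ± 0.84, Myog by 3.75 ± 0.88 and Cdkn1a by 3.70 ± 0.63. Of 22 denervation-induced genes 9 had a higher effect (12 adjusted over the list alone, 12 after centring, camera adjusted p = 2.9e-05, adjusted p = 0.62 with estimated correlation). Of 32 proteasome subunits 12 had a higher effect (26 adjusted over the list alone, 4 after centring, camera adjusted p = 1.7e-12, adjusted p = 0.23 with estimated correlation), with Psma5 at 1.18 ± 0.19 and Psmd4 at 1.09 ± 0.21. Of 21 antioxidant genes 9 had a higher effect and 1 a lower one (14 and 1 adjusted over the list alone, 9 and 1 after centring, camera adjusted p = 2.9e-07, adjusted p = 0.21 with estimated correlation), with Txn1 at 1.47 ± 0.17. Of 31 fatty acid genes 0 had a higher effect and 11 had a lower one (1 and 13 adjusted over the list alone, 0 and 14 after centring, camera adjusted p = 1.4e-10, adjusted p = 0.23 with estimated correlation), with Fabp3 at -2.94 ± 0.43. Of 48 respiratory chain genes 12 had a lower effect (25 adjusted over the list alone, 9 after centring, camera adjusted p = 4.4e-20, adjusted p = 0.31 with estimated correlation), with Cyc1 at -1.14 ± 0.21. Lower effects held also for Idh3a (-1.11), Mdh1 (-2.19), Bdh1 (-6.33 ± 0.46), Perm1 (-4.60 ± 0.39), Dok5 (-3.999), Myl2 (-3.80) and Lrrc52 (-7.95, which depends on the same offset). In all 782 genes passed, 423 higher and 359 lower (364 and 560 after centring). The count was 447 without the block, 1488 and 445 without sham mice 3 (its mouse number unsettled, r = -0.753 between its libraries' deviations) and 4, and 412, 353 and 411 without T9 mice 2, 3 and 4. Without sham mouse 4, whose triceps library held the 27.6 CPM of Myog, Myog (2.91, adjusted p = 0.057) and Chrnd (3.26, 0.052) did not pass. Without T9 mouse 3 Aif1l (adjusted p = 0.055), Chrnd (0.052) and Myog (0.071) did not pass, nor did Myog without T9 mice 1 (0.063) or 2 (0.057).

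The difference between T3 and T9 was larger in the gastrocnemius for the stress gene Gadd45b (2.07 ± 0.26, SE, limma adjusted p = 0.0096), the gluconeogenic enzyme Fbp2 (1.79 ± 0.21), the neurotrophin Ntf5 (1.70 ± 0.26) and Gm49794 (2.097 ± 0.32), the last chosen after its values were seen. In all 5 genes passed, with 812 at an unadjusted p under 0.05, and limma with voom weights on the recovered reads called 3. Without the block limma called 0. The count was 3, 0, 1 and 11 without T3 mice 1, 2, 3 and 4 and 2, 0 and 2 without T9 mice 2, 3 and 4. Of the genes named 0 of the 4 kept the call whichever mouse was left out. Without T3 mouse 2 Fbp2 had adjusted p = 0.055, Gadd45b 0.058, Ntf5 0.14 and Gm49794 0.15. Without T3 mouse 3 those p were 0.054 for Gadd45b, 0.1 for Ntf5 and 0.054 for Gm49794, and without T9 mouse 3 0.052 for Fbp2, 0.065 for Gadd45b, 0.18 for Ntf5 and 0.24 for Gm49794. Gadd45b did not pass without T9 mice 2 (0.062) or 4 (0.054). Ntf5 and Gm49794 did not pass without T3 mouse 1 (0.12 and 0.098) or T9 mice 1 (0.073 and 0.073), 2 (0.085 and 0.085) or 4 (0.2 and 0.2).

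In sham mice limma called nerve sheath genes higher in gastrocnemius than triceps. The myelin gene Mbp was higher by 2.68 ± 0.29 (SE, 4 mice, limma adjusted p = 0.00076) and periaxin, Prx, by 2.53 ± 0.35. Of 6 Schwann cell and nerve markers 4 were higher (4 adjusted over the list alone, 4 after centring, camera adjusted p = 0.022, adjusted p = 0.99 with estimated correlation). Rasd2 (3.57 ± 0.32), Six2 (3.15) and Cdh4 (2.78) were higher too, and Crnde (-2.19 ± 0.22), Tceal7 (-1.86), Ifi205 (-1.84), Tmem132b (-1.84) and Sbk3 (-1.60) lower. Of limb position genes, Hoxd8 stood at 1.10 ± 0.16 (adjusted p = 0.0051), Hoxd9 at 1.34 ± 0.20 (0.0051) and the hind limb factor Tbx4 at 0.57 ± 0.33 (0.17). Of 43 ribosomal protein genes 42 were lower (43 adjusted over the list alone, 43 after centring, camera adjusted p = 4.6e-25, adjusted p = 0.99 with estimated correlation). In all 4374 genes passed, 3020 higher and 1354 lower (1995 and 2270 after centring). The count was 96 without sham mouse 3 (mouse number unsettled) and 95 without the block, with chance not excluded. It was 9 without the mice of low-median libraries, losing most ribosomal calls and some of the 12 calls named here. Tmem132b had adjusted p = 0.056 without sham mouse 3.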

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

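No test in this part was chosen only after its result was seen. In groups of 4 or 6 libraries, the highest or lowest value was set against the nearest of the others with Dixon's test, for the named genes, the reads and the library medians. Of 506 sets of values 34 went past the 95% critical value, where chance gives about 1 in 20, or 25.30. Each value is given with the range of the other libraries of its group. Among the gastrocnemius sham libraries, replicate 2 had Amd1 at 1370.3 CPM (694 to 714), Aif1l at 0.936 CPM (1.99 to 2.32) and Lpl at 448 CPM (661 to 707), replicate 3 had Nrep at 85.6 CPM (119.6 to 126). Further, replicate 4 had Psmc4 at 78.6 CPM (93 to 96.3), Dok5 at 0.973 CPM (2.71 to 3.13) and Rasd2 at 31.2 CPM (50.02 to 54.5). Among the gastrocnemius T3 libraries, replicate 1 had Foxo1 at 94.1 CPM (67.3 to 70.6) and Myog at 9.22 CPM (52 to 70.9), replicate 2 had Hsp90ab1 at 3833 CPM (3269 to 3318). Further, replicate 3 had Eno3 at 2138 CPM (2676 to 2796) and Gdap1 at 3.8 CPM (2.16 to 2.27). Among the gastrocnemius T9 libraries, replicate 1 had Pgam2 at 1043 CPM (731 to 763), replicate 2 had Hspb7 at 790.0 CPM (553 to 583). Further, replicate 3 had Lyz2 at 12.2 CPM (18.2 to 19.5), replicate 4 had Aqp4 at 36.3 CPM (15.4 to 16.2). Among the triceps sham libraries, replicate 1 had Ighm at 21.5 CPM (36.2 to 45.4), replicate 2 had Myl2 at 62.6 CPM (179.7 to 319). Further, replicate 3 had Psmd4 at 248 CPM (156 to 178) and Chrnd at 0.336 CPM (1.43 to 3.19), replicate 4 had Lyz2 at 705 CPM (9.03 to 26), Ctss at 85.8 CPM (1.59 to 4.16), Myog at 27.6 CPM (2.96 to 5.49), Aif1l at 22 CPM (0.599 to 1.63), Lgals3 at 75.6 CPM (1.17 to 2.76) and Txn1 at 153 CPM (42.8 to 68.3). Among the triceps T3 libraries, replicate 4 had a median log2 value of 3.71 (3.99 to 4.07), replicate 5 had 88.8 M reads (15.7 to 23.4 M), Gpnmb at 38.4 CPM (7.39 to 13.1), Aqp4 at 1.89 CPM (6.14 to 11) and Gadd45b at 41.8 CPM (13.6 to 17.1). Further, replicate 6 had Mthfd2 at 6.27 CPM (11.5 to 15.8). Among the triceps T9 libraries, replicate 1 had Gpnmb at 0.434 CPM (1.04 to 1.74), replicate 4 had Aif1l at 11.5 CPM (1.55 to 2.28). Triceps sham replicate 4 stood apart in 6 sets, triceps T3 replicate 5 in 4 and gastrocnemius sham replicates 2 and 4 in 3 each.

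Effects that differed between muscles by the interaction test of limma, gastrocnemius minus triceps on the log2 scale in 4 mice per group, also stood out. After T3, 140 genes passed, among them Sox4 2.36, Fst 2.33, Cebpa 1.73, Blnk 1.71, Ccdc136 1.65, Lrrc52 -9.02, Bdh1 -6.73, Gbp10 -4.29, Myh2 -3.56, Dusp18 -3.51, Lpl -1.86, Ppara -2.41, Idh2 -1.75, Mdh1 -1.83. After T9, 782 genes passed, among them Aif1l 4.55, Chrnd 3.85, Gadd45a 3.79, Myog 3.75, Cdkn1a 3.70, Lrrc52 -7.95, Bdh1 -6.33, Perm1 -4.60, Dok5 -3.999, Myl2 -3.80, Mdh1 -2.19, Idh3a -1.11, Psma5 1.18, Psmd4 1.09, Fabp3 -2.94, Txn1 1.47, Cyc1 -1.14. For T3 against T9, 5 genes passed, among them Gadd45b 2.07, Fbp2 1.79, Ntf5 1.70, Gm49794 2.097. Values of Lrrc52 depend on the offset of 0.5 reads. Other splits of the 8 mice of each comparison were tested, 35 in all with the real one. For the T3 effect 2 of 35 splits gave at least 140 genes, the other one giving 210 with sham mice 1, 2 and 4 and T3 mouse 1 on 1 side, so chance was not excluded. For the T9 effect 1 of 35, the real split, gave as many as 782 genes (highest other 0 by limma), a share under 0.05. For T3 against T9 1 of 35, the real split, gave as many as 5, with 0 by limma in the highest other. That share is under 0.05 but rests on a count of 5, which fell to 0 without T3 mouse 2, T9 mouse 3 or the block, so it says little of these genes. With single mice left out the T3 count was as low as 54 (T3 mouse 3) and the T9 count 353 (T9 mouse 3) to 1488 (sham mouse 3).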

How the results depend on the processing

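Length and GC correction, the median as a covariate, both voom settings, leaving out the 4 low-median libraries and, for lists, leaving out each library were chosen only after the results were seen. Counts are of genes past the adjusted threshold by limma, T3 or T9 alone means against sham, T3-T9 means T3 against T9, and muscle-by means the difference between muscles. The main counts were gastrocnemius T3 3794, gastrocnemius T9 4864, gastrocnemius T3-T9 183, triceps T3 2624, triceps T9 1, triceps T3-T9 855, muscle-by-T3 140, muscle-by-T9 782, muscle-by-T3-T9 5, sham muscles 4374, with 102 list calls within muscles. Counts that moved over 1.5 times were, with quantile normalization, gastrocnemius T9 2719, triceps T9 2, muscle-by-T3 316 and muscle-by-T3-T9 24; with median centring, gastrocnemius T9 2639, triceps T9 2, muscle-by-T3 248 and muscle-by-T3-T9 19; with a pseudocount of 1 CPM, muscle-by-T3-T9 3. With library weights, gastrocnemius T3-T9 1403, triceps T9 230, triceps T3-T9 2300, muscle-by-T3 447, muscle-by-T9 2659 and muscle-by-T3-T9 922. With all 30 libraries in one fit, triceps T9 56. With only the 2 groups compared, gastrocnemius T3 2357, gastrocnemius T3-T9 1059 and triceps T9 2. With all 30 libraries and the mouse as a random effect, muscle-by-T3 337, muscle-by-T9 1287 and muscle-by-T3-T9 97. With only label number 57, triceps T3 684, triceps T9 0 and triceps T3-T9 314. With only label number 60, triceps T3 1247 and triceps T3-T9 50. With an estimated correlation, lists 2. With the length and GC trend removed, gastrocnemius T3-T9 645, triceps T9 7, triceps T3-T9 1894, muscle-by-T3 681, muscle-by-T9 1986, muscle-by-T3-T9 88 and sham muscles 2358. With the median covariate, gastrocnemius T3 2079, gastrocnemius T9 1388, gastrocnemius T3-T9 423, triceps T9 15, triceps T3-T9 2212, muscle-by-T3 1298, muscle-by-T9 3208, muscle-by-T3-T9 388 and sham muscles 308. With voom weights, triceps T9 0 and muscle-by-T3-T9 3. With voom weights and median-of-ratios scaling, gastrocnemius T9 2675, triceps T9 0, muscle-by-T3 232 and muscle-by-T3-T9 17. With the 4 low-median libraries left out, gastrocnemius T3-T9 563, muscle-by-T3 39, muscle-by-T9 327, muscle-by-T3-T9 36 and sham muscles 9. Within label numbers and without low-median libraries fewer libraries were fitted. For each of the other changes the cause was not tested.

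Within a muscle, libraries of the same number did not pair (13 of 30 pairs with r above 0.1, mean 0.091, and 9 of 30 replicates correlating best with their own number). With the replicate block the counts were gastrocnemius T3 3370, gastrocnemius T9 4430, gastrocnemius T3-T9 70, triceps T3 2366, triceps T9 0, triceps T3-T9 688, and 105 list calls. Of named genes 9 lost their call under this block, among them Psmd4 and Chrna1 in gastrocnemius T3-T9 (adjusted p = 0.085 and 0.089), and the TCA cycle list of triceps T3 had adjusted p = 0.061. Between muscles the mouse pairs the libraries, and with no block for the mouse, muscle-by-T3 75, muscle-by-T9 447, muscle-by-T3-T9 0 and sham muscles 95.

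Leaving out each library in turn gave gastrocnemius T3 2661 to 4765, gastrocnemius T9 3384 to 5589, gastrocnemius T3-T9 11 to 194, triceps T3 1865 to 3122, triceps T9 0 to 7, triceps T3-T9 539 to 1066, muscle-by-T3 54 to 183, muscle-by-T9 353 to 1488, muscle-by-T3-T9 0 to 11, sham muscles 96 to 4552, lists 99 to 108. Of 265 named gene values, 247 past the threshold, 160 kept direction and side in each alternative run. Over 6823 alternatives 6487 kept both, 319 lost the call, 14 gained one and 3 reversed, all of them Lgals3 in triceps T3, from -0.10 to 1.38 with label number 57 alone, 0.83 with the 4 low-median libraries left out and 0.80 without triceps sham replicate 4 (lowest with 1 left out -0.34). Of 86 list results 6 kept both in each alternative run. Over 2034 alternatives 1833 kept both, 163 lost the call, 22 gained one and 16 reversed. A list's value is its mean log2 change minus that of other genes. The respiratory chain of triceps T3 (-0.30) went to -0.30 with fry, 0.24 with the median covariate and -0.019 with the 4 low-median libraries left out. Ribosomal proteins went to 0.78 with the median covariate, 0.043 with the 4 low-median libraries left out and 0.043 without gastrocnemius sham replicate 4 (lowest with 1 left out -0.68) for gastrocnemius T3 (-0.38), -0.35 with fry, 1.33 with the median covariate, 0.075 with the 4 low-median libraries left out and 0.075 without gastrocnemius sham replicate 4 (lowest with 1 left out -0.65) for gastrocnemius T9 (-0.35), 0.29 with the median covariate and 0.020 with the 4 low-median libraries left out for triceps T3 (-0.54) and 0.16 with the median covariate for triceps T9 (-0.45). Macrophage markers went to 0.19 with the 4 low-median libraries left out and 0.20 without triceps sham replicate 4 (lowest with 1 left out -0.76) for triceps T9 (-0.50) and 1.01 with the median covariate for gastrocnemius T9 (0.17). With fry, for the macrophage markers of gastrocnemius T9 (adjusted p = 0.031, a call gained) and for the respiratory chain without the low-median libraries, the value kept its sign and only the test's direction turned. The cause of these reversals was not tested. Depth limits genes near 0 reads, as Lrrc52 in the injured gastrocnemius.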

Other observations

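Tests chosen only after the result was seen were those of transcript length, scaling, low-median libraries, the median as a covariate and muscle for the respiratory chain, all 3 for Cd68, those of label number, low-median libraries and injury level for the triceps counts, the splits within mice, and the lists with a library left out, though the fits of each label number were chosen beforehand. Of 20 heat shock genes 6 rose and 0 fell (6 and 0 adjusted over the list alone, 5 and 1 after centring, camera adjusted p = 0.26, adjusted p = 0.83 with estimated correlation) in the gastrocnemius after T3, and of the same list 11 rose and 1 fell (12 and 1 adjusted over the list alone, 4 and 1 after centring, camera adjusted p = 0.32, adjusted p = 0.83 with estimated correlation) after T9. The small heat shock protein Hspb7 rose by 1.65 ± 0.24 and 1.20 ± 0.24 (SE, n = 4) and Hsp90ab1, which encodes a cytosolic chaperone, by 1.56 ± 0.21 and 1.45 ± 0.21. In the triceps after T3, of 20 heat shock genes 8 rose and 0 fell (8 and 0 adjusted over the list alone, 5 and 2 after centring, camera adjusted p = 0.12, adjusted p = 0.79 with estimated correlation), with Hspb7 at 2.46 ± 0.27 and Cryab at 1.42 ± 0.19 (n = 6). After T9 limma passed 0 of the triceps' 20 heat shock genes, with 8 at an unadjusted p under 0.05 and 4 higher adjusted over the list alone, and the list ranked higher (camera adjusted p = 0.045, adjusted p = 0.96 with estimated correlation). It was not called without sham replicates 2 (adjusted p = 0.072), 3 (0.056), 4 (0.19) or 6 (0.075), T3 replicates 1 (0.055) or 4 (0.062), or T9 replicates 3 (0.069), 4 (0.24) or 5 (0.074), with the replicate block (0.052), with the median covariate (0.27) or without the 4 low-median libraries (0.28). Of 19 circadian clock genes 9 rose and 2 fell (9 and 2 adjusted over the list alone, 7 and 2 after centring, camera adjusted p = 0.3, adjusted p = 0.83 with estimated correlation) in the gastrocnemius after T3, and 6 rose and 1 fell (6 and 1 adjusted over the list alone, 3 and 3 after centring, camera adjusted p = 0.84, adjusted p = 0.96 with estimated correlation) after T9, where the list's median of 0.51 was positive and its rank below other genes. Of the clock genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, 4 and 1 after centring, camera adjusted p = 0.51, adjusted p = 0.95 with estimated correlation) in the triceps after T3. The repressor Cry2 rose by 1.35 ± 0.26, 1.40 ± 0.26 and 1.51 ± 0.34 in these comparisons, and the nuclear receptor Rora by 0.79 ± 0.14 and 0.92 ± 0.14 in the gastrocnemius after T3 and T9. Per1 rose by 1.61 ± 0.46 in the triceps after T3 and did not pass without T3 replicate 5 (adjusted p = 0.053).

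Genes of myostatin, activin and BMP signalling rose in the gastrocnemius after T9. Of 20 such genes 12 rose (13 adjusted over the list alone, 6 after centring, camera adjusted p = 0.03, adjusted p = 0.69 with estimated correlation), not called with the median covariate (0.78), with Fst, an antagonist of activins, at 2.37 ± 0.38, Smad3 at 1.95 ± 0.27 and myostatin itself, Mstn, at 1.04 ± 0.21 (SE, n = 4). Of the same list 8 rose and 1 fell (11 and 1 adjusted over the list alone, 5 and 1 after centring, camera adjusted p = 0.16, adjusted p = 0.83 with estimated correlation) after T3, with Fst at 1.92 ± 0.38. Of 26 interferon-stimulated genes 2 rose and 1 fell (2 and 0 adjusted over the list alone, 2 and 2 after centring, camera adjusted p = 0.7, adjusted p = 0.93 with estimated correlation) in the gastrocnemius after T3, 3 rose and 0 fell (0 and 0 adjusted over the list alone, 0 and 2 after centring, camera adjusted p = 0.052, adjusted p = 0.77 with estimated correlation) after T9 and in the triceps after T3 no member passed by limma (4 at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone, 0 and 3 after centring, camera adjusted p = 0.065, adjusted p = 0.79 with estimated correlation). Their medians of 0.25, 0.07 and 0.07 were positive and each list ranked below other genes. The list was called lower after T9 without gastrocnemius sham replicates 1 (adjusted p = 0.049), 2 (0.048) or 4 (0.014), T3 replicate 2 (0.049) or T9 replicates 3 (0.044) and 4 (0.0026). In the triceps after T3 it was called lower without sham replicates 1 (0.036) or 2 (0.04) or T3 replicates 1 (0.035), 2 (0.025) or 5 (0.0017).

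Other splits of the libraries into groups of the same sizes were tested for each count. In the gastrocnemius 1 of 35 splits, the real one, gave as many genes in each comparison, the lowest share 35 splits allow. T3 gave 3794 (highest other 3), T9 4864 and T3 against T9 183 (highest other 0 by limma for both). In the triceps 2 of 100 splits gave as many as the 2624 genes of T3, a share under 0.05, and the other gave 2994. That split set sham replicates 1, 3, 4 and 5 with T3 replicates 4 and 6, with both low-median libraries on 1 side as in the real split, and so points to a structure of the samples that the share does not exclude. For T9 2 of 100 splits gave at least the 1 gene called, the other with 3763 genes, several times the real count. That share is under 0.05 but rests on a count of 1, which fell to 0 without T9 replicates 1, 2 or 4, with voom weights and with the replicate block, so it says little of the single gene. The other split set sham replicates 1 to 4 with T9 replicates 1 and 5, with the 3 low-median libraries on 1 side, and so points to a structure of the samples. For T3 against T9 in the triceps 1 of 100, the real one, gave as many genes (855, highest other 0 by limma), a share under 0.05. Between muscles of sham mice, without the mouse as a block, 5 of 35 splits gave at least the real 95, so chance was not excluded, and those with 7213, 5649 and 5026 genes put the 3 low-median libraries on 1 side, a structure of the samples. With the block the 8 splits are too few for a share under 0.05, with 4374 genes in the real one and 0 in the highest other.

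Nuclear-encoded respiratory chain genes were lower in the gastrocnemius after T9, 40 of 48 with a median of -0.83. With the trend on transcript length and GC removed 46 were lower, which argues against that trend as the whole cause. Without sham replicate 4, the only low-median library of this muscle, 40 were lower, which argues against that library as the whole cause. The 11200 other genes had a median of 0.40, above the members' upper quartile of -0.62. The list was known to rank lower, so this is no test of scaling. With the median covariate the list stood -0.12 from other genes (adjusted p = 0.13), and since every T9 median lay above every sham median, a tie to the library median stays open. An effect of the injury specific to this muscle stays open, since 12 of the members had a lower T9 effect than in the triceps by the interaction test, between the bounds set for and against it.

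Cd68 rose in the triceps after T3 and a candidate explanation was more macrophages in the muscle. The other 9 macrophage markers had a median of -0.25 (quartiles -0.86 and -0.10), and 0.22 (-0.18 and 0.53) without triceps sham replicate 4, the library with 705 CPM of Lyz2. Without that library Cd68 stood at 4.46 ± 0.52, Gpnmb, which macrophages also express, at 4.36, and 1 of the 9 passed, Lgals3 at 0.80 (adjusted p = 0.029), so the markers argue against more macrophages as the whole cause, and a change within macrophages stays open. Cd68 lies on chromosome 11 of GRCm38, 69664213 to 69666153, 782 bases from Eif4a1 on the same strand, and its log2 ratio to Eif4a1 rose by 2.64 (95% interval 1.21 to 4.08), which argues against a fixed share of reads running on from that gene. The rise may belong to a wider one of lysosomal genes, since 15 of 30 autophagy and lysosome genes rose.

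In the triceps, 2624 genes changed after T3 and 1 after T9 by limma. The median within-group SD of a gene was 0.313 in T3, 0.314 in T9 (1.025 times T3 at the median) and 0.402 in sham. The fit pools the groups' variance, so these SDs cannot test the cause. Label number 57 alone gave 684 genes after T3 and 0 after T9, number 60 alone 1247 and 1, and leaving out the low-median libraries of the triceps 1977 and 1, which argues against either as the whole cause. The direct test of T3 against T9 called 855 genes, 785 of them among those changed after T3, so a difference between the injuries is not shown for the others of these. For the genes it called, the level of the injury may set the difference, as a hypothesis found and tested on these data.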
